A study of Mus musculus with 2 samples.

How the data were processed

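Genomic DNA of mouse embryonic stem cells was sheared, 5fC was tagged with biotin and captured on streptavidin beads, and the captured DNA was deaminated with A3A and amplified by PCR, per the labels' protocols. The 2 libraries form 1 group, with replicate numbers taken from their titles. No label says that they came from separate cultures. The submitters' processing notes name cutadapt 4.1, FastQC 0.11.9, Bismark 0.23.1, Bowtie2 2.4.5, SAMtools and the mm10 build, with no role or order. Whether duplicate reads were removed, and whether libraries were pooled at any step, is not given in the sources used here.

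For each listed cytosine the authors deposited the count of reads that kept the C, the count of reads that did not, and their sum, per the file headers, as raw counts. The authors also deposited a p-value for each cytosine with its Holm and Benjamini-Hochberg adjusted p-values, per the file headers. Only called sites are listed: in both libraries each site had a depth of at least 30 and an adjusted p below 0.05, so levels at uncalled cytosines were not analysed here. Low levels are thereby left out, and the median level of called sites is higher than that of all cytosines. The deposited p-values equal the binomial probability of exactly the listed count at a background rate of 6.93% in both libraries, not the probability of that count or more. The tail probability was up to 1.67 times larger in replicate 1 and 1.68 times in replicate 2, and exceeded the largest listed p at 603 and 634 sites. The Holm values imply that 3452701 and 3863295 cytosines were tested.

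The level was computed as the count of reads that kept the C over the depth. At 34 reads, the median depth, a level is known only roughly, and 95% Wilson intervals are given. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and Fisher tests cover counting error only. Sites were matched between libraries by chromosome, position and strand. Chance overlap was taken as the product of the numbers of called sites over the larger number of tested cytosines. Independent libraries were simulated 100 times with the pooled level of each site and equal expected depth in both libraries, an assumption that real libraries need not meet. The share of sites called again in an independent library was simulated 20 times on the same assumption, from each site's own level and depth. Shared sites were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. This test and the list test were tested on simulated data with known answers. Lists of 20 long genes with no added hits were called in 6.50% of 200 simulated lists, and lists of 20 genes with 8 added hits in 100%. Hit rates there were assumed from gene length, and lists were called on an unadjusted p under 0.05. Fewer added hits were not simulated, so the power for small excesses is not known. Lists of very long genes can still be called through their length, as described with the processing.

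Genes were taken from a RefSeq table of GRCm38, the same build as mm10, as gene start and end with 2 kb on both sides, so that a site counted for a gene can lie in its flank, since strand, exons and the genome sequence were not used here. Lists were tested against 10000 random lists matched on 10 bins of gene length, two-sided, drawn from 34614 protein-coding and long noncoding RNA genes. Sites per Mb were computed up to the end of the last annotated gene of each chromosome. Chance for clustering came from moving sites within 100 kb, and chance for genes from moving sites by 100 kb to 1 Mb. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

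The tests, gene lists, alternatives and the rule for named items were set before the data were examined. The rule takes the 10 CG and 5 non-CG shared sites with the highest lower level of the replicates, ties broken by the higher total depth, the 5 shared sites with the lowest Fisher p, the CpGs called on both strands in both replicates, the 15 protein-coding genes with the most shared CG sites, and up to 4 genes per list. The genes with the most shared sites of any context and the dense windows were chosen after the values were seen. Some planned steps were changed or left out. A mean ± SD over the replicates was planned and is not given as the error of a result, because the libraries agree within sampling noise at shared sites. Promoter, UTR and exon shares, the base before the cytosine, chance overlap from nearby cytosines and matching on CpG number were not run. Gene lists were matched on length in place of CpG number. Alternatives were stricter thresholds, a higher depth, a level minimum, other distances, each replicate alone, and, added after the data were seen, results outside dense windows, sites of any context, finer length bins, and identical counts, dyads and CG shares by depth, window and partner site.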

Results

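5-formylcytosine (5fC), an oxidised form of methylated cytosine made by the TET enzymes, was mapped base by base in mouse embryonic stem cells, the pluripotent cells of the early embryo grown in culture. In CLED-seq, the method used, 5fC is tagged with biotin, the tagged fragments are captured, and the deaminase A3A then converts unlabelled cytosines, so that a cytosine still read as C marks a candidate 5fC. There were 2 libraries, labelled replicates 1 and 2, in 1 group, with no control library among the samples, so no condition could be compared with another. Replicate 1 listed 28569 called cytosines and replicate 2 listed 29650, each covered by at least 30 reads. Median depth at a called site was 34 reads in both (quartiles 31 and 38), and the reads at listed sites summed to 1039807 and 1078502. These sums cover called sites and are not the depth of the libraries. The share of reads at a site that kept the C is called its level here. It is a share among captured fragments and not the share of genomic copies that carry 5fC.

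Most called cytosines lay outside CG at their listed positions. The CG share of the tested cytosines is not known, so the shares given here show neither enrichment nor depletion of CG. Unconverted cytosine could not be told apart from modification, as described under other observations. Calls in any context, and those outside CG in particular, are therefore candidates only. CG sites made up 8.01% of the calls in replicate 1 (95% Wilson interval 7.70 to 8.33) and 8.20% in replicate 2 (7.90 to 8.52). At a depth of at least 50 the CG share was 13.2% and 13.8%, and 9.60% and 9.77% at that depth outside 13 site-dense windows described with the chromosomes. Context follows from the exact position, and 21.0% of the sites that replicate 1 alone listed outside those windows had a near-equal partner at another position in replicate 2, as described with the replicates. CG sites were 9.71% of those with a partner (8.77 to 10.7), 6.61% of those without (6.20 to 7.05) and 8.01% of shared sites outside the windows (7.52 to 8.53). CHG sites, in which H is any base but G, made up 24.7% and 24.2%, and CHH sites 67.3% and 67.6%. The median level was 46.7% in replicate 1 and 46.2% in replicate 2. At CG sites it was 45.2% and 45.5%, against 46.7% and 46.3% at the other sites, a mean difference of -1.20 points. That difference turned to 1.39 points outside the dense windows, so no direction is given to it. Levels of at least 80% were found at 22.0% and 21.5% of calls, and every read kept the C at 1135 and 1158 sites.

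**Figure D1:**
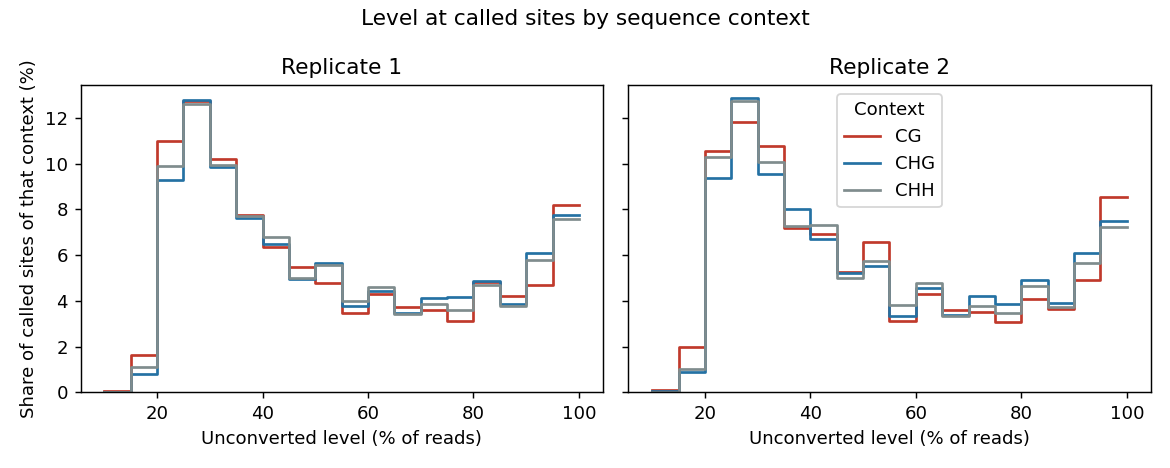
Share of called sites (y axis, % of the sites of that context) by level (x axis, % of reads that kept the C, in steps of 5 points) for CG, CHG and CHH sites in each replicate. The 3 contexts follow nearly the same curve in both replicates, with most sites between 20% and 50% and a smaller rise toward 100%.

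At 45 shared CG sites every read kept the C in both replicates, and the 10 of these with the greatest summed depth are named. They included a site in Trmt1, which encodes a tRNA methyltransferase, at chromosome 8 position 84690543 (87 reads in replicate 1 and 56 in replicate 2; Wilson lower bounds 95.8% and 93.6%). A site in Cdk6, a cell-cycle kinase gene, lay at chromosome 5 position 3343866 with 75 and 38 reads. Further sites lay in Zmpste24, whose protease processes lamin A (chromosome 4 position 121062501; 68 and 34 reads), in Pstpip2, Sgpp2 and Pxdn, and in the potassium channel gene Kcnc1. Another lay 242 bp outside Kmt2c, which encodes a histone methyltransferase. On chromosome 10, a site at position 70640101 lay in the long noncoding RNA genes D630013N20Rik and Gm51772, 40810 bp from Phyhipl. Of the 10, the site farthest from a protein-coding gene lay on chromosome X at position 21853035, 110677 bp from Slc6a14. Except at Trmt1, Cdk6 and Zmpste24, the read counts at these sites were the same in both replicates, from 39 to 51 reads. Counts at shared sites were alike beyond sampling noise, so agreement of the replicates is not independent evidence for these levels. Among the non-CG sites, Dtx2, Creb3l1 and the checkpoint kinase gene Chek2 held sites at 100% in both replicates, with at least 33 reads behind each value. Across all shared sites, 458 kept the C in every read of both replicates, and 45 of these were CG. Coordinates are those of mm10.

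Among protein-coding genes, 4858 of 21887 held at least 1 site called in both replicates within the gene or 2 kb on either side, and 691 held a shared CG site. Zc3h7a, a zinc finger gene on chromosome 16 (11136594 to 11176393), had the most, 5 shared CG sites, with mean levels over its 9 shared sites of 36.7% and 34.8%. Most of its calls fell in a single site-dense window. Mical3, which encodes an actin-oxidising enzyme, held 3 shared CG sites on chromosome 6, with mean levels of 59.1% and 59.2% over 5 shared sites. The window of Tpi1, the gene of the glycolytic enzyme triosephosphate isomerase, also held 3, at mean levels of 43.5% and 43.3%, but 0 of them lay inside the gene (chromosome 6, 124810586 to 124814158) and all lay in its 2 kb flanks. The other 26 genes with more than 1 shared CG site were tied at 2, so those named from them were taken in alphabetical order. They included the cholesterol transporter gene Abcg1 (46.2% in both), the haematopoietic regulator Gata2 (49.6% in both) and the imprinted adaptor gene Grb10 (66.1% in both), with means over those 2 sites. The homeobox gene Cux1 was tied with them, and its mean was 59.8% in both over 5 shared sites, of which 2 were CG. With sites of any context, Sfi1 had 25 shared sites, Wwox 16, Gse1 14 and Camta1 12, and most of the genes with many sites were long.

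Shared CG sites were compared with random gene lists of the same size and matched length for 10 lists written before the data were examined, and 0 of the 10 passed Benjamini-Hochberg adjustment at 0.05. The polycomb, trithorax and histone demethylase genes came closest, with 5 of 25 genes hit (Kdm6b, Kmt2a, Kmt2c, Kmt2d and Ezh1) against 1.07 expected (permutation p = 0.00700, adjusted p = 0.0700). When this list was matched on 200 length bins, 1.23 were expected and the adjusted p was 0.102 (permutation test). With sites at an adjusted p under 0.01, the adjusted p of the list was 0.0580 (permutation test). The sites counted for Kmt2c and Ezh1 lay in the flanks and not inside the gene. Of the pluripotency genes, 2 of 26 were hit against 0.584 expected, Klf4 at 33.3% and Klf5 at 25% in both replicates. Among the genes of cytosine methylation and its removal, 1 of 25 was hit, the DNA methyltransferase gene Dnmt3a. Tet1, whose product makes 5fC, held 1 shared non-CG site at 25.8% in both replicates. The lineage regulators had 1 of 32 hit, Pax7, and the imprinted genes 1 of 27, Grb10. Neuronal adhesion and channel genes had 2 of 20 hit, Cntn5 and Lrrc4c, against 1.38 expected. With the finer matching on 200 length bins, 2.85 were expected for the neuronal list. Germline genes, ribosomal protein genes and liver and blood genes each had 0 of 20 hit, and the fibroblast genes 0 of 15, a list kept for feeder cells. The expected number was below 1 in those lists, so a low count could not be told from chance.

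CG sites lay in protein-coding genes more often than sites moved at random along the chromosome, at 58.0% in replicate 1 and 58.3% in replicate 2 against means of 47.3% and 47.2%, and above the highest of 100 draws in each (49.3% and 49.4%). At a depth of at least 50 the shares were 41.4% and 41.6%, within the range of the moved sites at that depth (means 37.7% and 37.5%, highest 44.3% and 45.2%), so the difference was not detectable there. Outside the dense windows at that depth they were 73.9% and 73.5%, above the highest draws of 60.4% and 61.5%. Non-CG sites were at 51.7% and 51.9%, against 47.1% and 47.2%. The Wilson intervals of CG and non-CG sites did not overlap in either replicate. The moved positions were not matched for CpG or for coverage. The share of all covered CpGs that lie in genes is not known. These comparisons therefore do not show a preference of the modification for genes. Outside the dense windows, autosomes held a median of 11 and 11.4 called sites per Mb, from 7.83 on chromosome 3 to 16.5 on chromosome 11 in replicate 1. Chromosome X held 2.78 and 2.89 per Mb, which is 0.254 of the autosome median in both, and chromosome Y 0.330 and 0.308. Over the 19 autosomes, site density followed protein-coding gene density (Pearson r = 0.650 and 0.663, permutation p = 0.00348 and 0.00271; Spearman rho = 0.821 and 0.828, permutation p = 5e-05 and 4e-05). The adjusted p values were 0.00348 for r and 5e-05 for rho over both replicates. Without chromosomes 7 and 11, the farthest in gene density, r was 0.606 and 0.591.

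**Figure D2:**
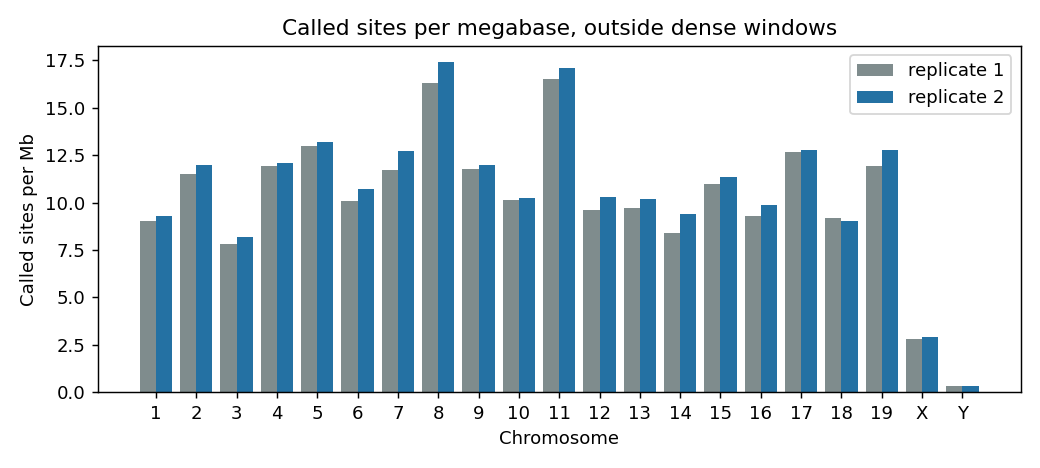
Called sites per Mb (y axis) on each chromosome (x axis) outside the dense windows, with a bar for each replicate. Chromosome X stands at 2.78 and 2.89 per Mb and chromosome Y near 0.3, below every autosome. The number of cytosines covered on each chromosome is not known.

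A small part of the calls was packed into 13 windows of 10 kb, 2.81% of sites in replicate 1 and 2.48% in replicate 2. The window with the most sites, chromosome 17 from 39840000 to 39849999, held 291 and 316 sites and overlaps the ribosomal RNA pseudogene Rn18s-rs5 and the RNA gene AY036118. Rn18s-rs5 spans 39846354 to 39848202, only a part of the window. CG sites made up 33.7% and 38.6% of the calls in this window, and its median level was 28.8% and 26.8%. The start of chromosome 9, from 3000000 to 3039999, held 4 such windows with median levels between 19.4% and 21.9%. Windows at chromosome 2 position 98660000 and chromosome 14 position 19410000 had median depths of 71 to 93 reads. Parts of Sfi1 and Zc3h7a fell in further windows. The rule of at least 10 sites per window was chosen after the data were seen.

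The replicates shared 11542 sites, 40.4% of replicate 1 and 38.9% of replicate 2, where 219 would be shared by chance over the 3863295 cytosines tested in replicate 2. Listed sites also had a depth of at least 30. How many tested cytosines had that depth is not known, so 219 can be too low by an unknown factor. At shared sites the levels were alike beyond sampling noise. Counts of both reads that kept the C and reads that lost it were identical at 70.6% of shared sites (Wilson interval 69.7 to 71.4). In 100 simulated pairs of independent libraries the mean was 1.10% and the highest 1.33%. The chi-square of the counts per degree of freedom was 0.0611, and Pearson's r across sites, which are not independent replicates, was 0.997, against at most 0.934 in the simulation. The replicates thus differed by less than the sampling noise at shared sites and were counted there as 1 sample. Values are therefore given for each library with no SD between replicates as a biological error. Identical counts were found at 72.9% of the 11165 shared sites outside the dense windows and at 2.12% of the 377 inside them. Where either replicate had a depth of at least 50, they were found at 17.3% of 826 sites, against at most 1.33% simulated. Inside the dense windows at that depth the share was 0.909% of 220 sites, within the simulated range (highest 1.36%).

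**Figure D3:**
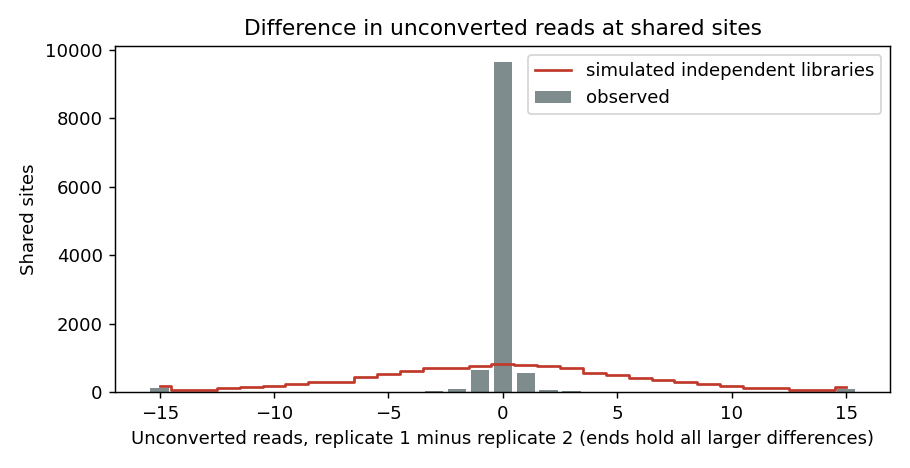
Number of shared sites (y axis) by the difference in reads that kept the C, replicate 1 minus replicate 2 (x axis, in reads), observed (bars) and in a pair of independent libraries simulated with no depth minimum (line). The observed sites stand mostly at 0, where the 83.5% with the same number of such reads lie, while the simulated sites spread over several reads to each side.

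Fisher's exact test per site (two-sided, Benjamini-Hochberg at 0.05) found 3 of the 11542 shared sites to differ, and 27 had an unadjusted p under 0.05. Of the 3, 2 lay in the dense windows, on chromosomes 12 and 17. On chromosome 12 at position 120028838, 7596 bp from Tmem196, the level was 30.7% in replicate 1 and 75.3% in replicate 2 (adjusted p = 0.000324, Fisher's exact test). The site on chromosome 19 at position 61331453 stood at 39.0% and 88.9% (adjusted p = 0.000904, Fisher's exact test). The site at chromosome 17 position 39844104, in the window that overlaps Rn18s-rs5 but outside that gene, stood at 60.0% and 18.8% (adjusted p = 0.00522, Fisher's exact test). In shared sites simulated with independent counts, a shift of 20 points was recovered at 0% of changed sites and a shift of 40 points at 43.5%. The test and this simulation assume independent counts, while the observed counts were alike beyond sampling noise. Sensitivity was low even in the simulation, and its value in these data is not known. The adjusted p-values of the 3 sites rest on the same assumption. Of the CpGs with a call, 10 of 2278 in replicate 1 and 10 of 2422 in replicate 2 were called on both strands (0.439% and 0.413%). Most of these lay in the dense windows, and outside them 2 of 2098 and 1 of 2223 were called on both strands (0.0953% and 0.0450%). Only called sites are listed, so whether the opposite cytosine was covered is not known. A low share therefore does not show that the opposite strand was unmodified. The CpG called on both strands in both replicates lay in the same chromosome 17 window, also outside Rn18s-rs5, at positions 39845714 and 39845715. Its level was 19.4% and 20.8% on the plus strand and 29.4% and 22.9% on the minus strand. Another called site lay within 100 bp of 4.15% and 4.12% of sites, against 0.916% and 0.840% by chance. Outside the dense windows these shares were 1.59% and 1.85%, against 0.368% and 0.380%. The moved positions were not matched for coverage and need not be cytosines. The excess over chance therefore does not show that the modification itself is clustered.

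Many sites called in only 1 replicate had a counterpart at another position in the other replicate. Outside the dense windows, 2820 pairs of such sites, with 1 site from each replicate, lay 91 to 120 bp apart, and 83.4% of them had counts within 1 read of each other. Within replicate 1, 40 pairs lay at that distance, 35% of them near-equal, and within replicate 2 there were 40, 7.50% of them near-equal. Beyond that distance, up to 150 bp, 26 pairs between replicates were found. Of the 16602 sites outside the dense windows that replicate 1 listed and replicate 2 did not, 2346 (14.1%) had a near-equal partner at 91 to 120 bp. Over any distance up to 120 bp 3492 (21.0%) had one, of which 725 had one within 5 bp. At 1 to 5 bp, 77.8% of 935 pairs between replicates were near-equal, against 44% of 25 within replicate 1 and 54.8% of 31 within replicate 2.

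**Figure D4:**
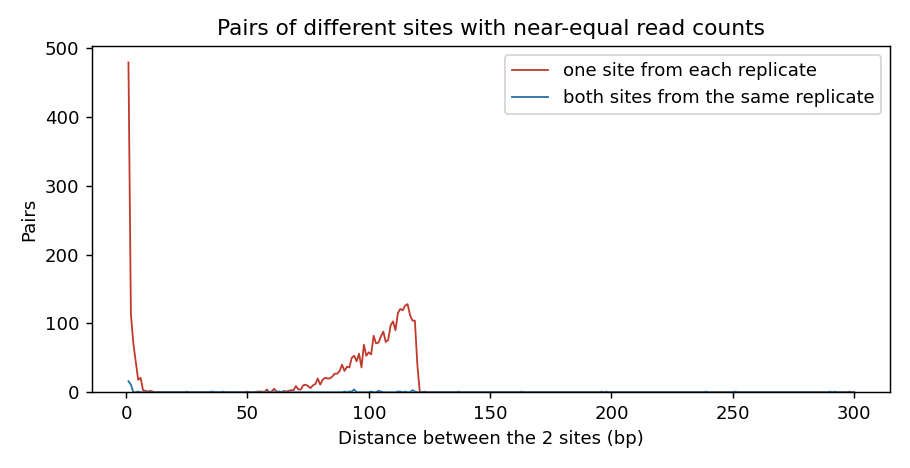
Number of pairs of different sites with near-equal counts (y axis) by the distance between them in bp (x axis), for pairs with a site from each replicate and for pairs within a replicate. Pairs between replicates gather at the shortest distances and between 61 and 120 bp, then end, and pairs within a replicate stay near 0.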

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

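Results outside dense windows, and the list tests with sites of any context or with 200 length bins, were chosen after seeing the data; the other alternatives were planned. Of the alternatives, 51 left a value within its spread or within 1.5 times of a count, 26 moved it and 1 turned its sign. For the median level and the CG minus non-CG difference, the spread was the SD of the 2 replicates (0.363 and 0.437 points). Each replicate must lie within that SD of their mean, so leaving a replicate out could not move these values. That SD is a yardstick only and not a biological error. At a depth of at least 50, 1589 sites per replicate and 480 shared sites remained by construction, the CG share was 13.5%, the median level 34.2%, the CG minus non-CG difference -3.70 points, the correlation 0.979, dyads called on both strands 1.17% and CG sites in protein-coding genes 41.5%. With an adjusted p under 0.01 the median level was 51.4% and clustering within 100 bp 3.57%; under 0.001 the median level was 57.7%, the difference -2.28 points and dyads 0.221%. A stricter threshold removes low levels by construction. With a level of at least 20% the difference was -0.747 points and clustering 3.52%. Outside the dense windows the CG share was 7.63%, the median level 47.1%, the difference 1.39 points, sites that differ between replicates 1, dyads 0.0702%, CG sites in protein-coding genes 62.9% and clustering 1.72%. Clustering was 3.36% within 50 bp, 5.28% within 200 bp, 3.37% on the same strand and 7.71% for CG sites. The cause of the other shifts was not tested. With sites of any context, 1 of the 10 lists passed in place of 0, the neuronal genes (18 of 20 against 10.3 expected, permutation test, adjusted p = 0.010). These are long genes, and with 200 length bins 16.5 were expected and the adjusted p was 0.717, so the call was lost with finer length matching. Over all, 10 settings of the list test were run, 100 tests in all. Without a replicate, the number of sites lay between 28569 and 29650 and the CG share between 8.01% and 8.20%. No paired analysis was possible because there is only 1 group. Promoter windows and the base before the cytosine were not run. A depth near 34 reads limits the precision of each level.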

Other observations

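All tests in this part were chosen after the result they address had been seen, except that of identical counts by chromosome. The bounds used for near-equal pairs, sharing near the threshold, opposite strands and the ratios of trinucleotides were also set after looking at the data, and the reading of the CGG to CCG ratio against the CTG to CAG ratio was adopted after both were known. The rules by which unequal depth and doubtful positions leave an explanation open were also added after the results were known. The design has 1 group, so no biological explanation was tested.

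Genes with at least 3 shared sites were ranked by shared sites per 100 kb, counted over the gene and its 2 kb flanks. Such a ranking puts short genes first by construction, so their shortness is not a result. Around Inha, which encodes a subunit of the hormone inhibin, there were 3 shared sites, 41.2 per 100 kb of that window, 0 of them CG and 1 inside the gene, at a mean of 48.6% in both replicates. Sfi1, a longer gene of 71498 bp that lay partly in dense windows, held 33.1 per 100 kb. Sema4c, a semaphorin gene, held 4 at 68.3% and 68.9%, and Rapsn, whose product clusters acetylcholine receptors, 3 at 87.9% and 87.0%, each inside the gene. These genes were ranked after their values were seen, and no test was made.

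Identical counts were found at 70.6% of shared sites, which argues against independent libraries that measure the same level, where at most 1.33% was simulated. This does not cover deep sites in the dense windows, where 0.909% of 220 sites were identical and independent libraries gave up to 1.36%. A file deposited again under another name is argued against, since 40.4% of replicate 1 sites are listed in replicate 2. Shared reads or molecules stay open: the lowest of chromosomes 1 to 19 and X stood at 54.1% identical, but the share over all sites made a high value on each chromosome unavoidable, so this test decides nothing.

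Near-equal counts at 83.4% of pairs 91 to 120 bp apart, against at most 35% within a replicate, argue against a chance likeness of nearby sites at that distance. At 1 to 5 bp the share was 77.8% against at most 54.8%, too close to decide whether any sites so near have like counts. The number of pairs at 1 to 5 bp was 935 between replicates, against 25 within replicate 1 and 31 within replicate 2. That excess argues against sites that lie so near each other by chance. As listed, 46.0% of near-equal pairs 61 to 120 bp apart lie on opposite strands, so they are not all cytosines on the same strand of the same reads. Sharing hardly rose away from the threshold, by 2.89 points from a depth of 30 (37.6%) to at least 50 (40.5%) in replicate 1 and 5.77 points in replicate 2, and by 7.68 and 8.65 points from levels under 30% to at least 80%, which argues against chance near the threshold as the main cause. Sites with a depth of at least 50 and a level of at least 80% were shared in 42.3% (replicate 1) and 38.7% (replicate 2) of cases against at least 99.6% simulated at equal depth, but depth at unlisted sites is not known and at 39.6% of the 96 such shared sites replicate 2 had under 60% of the depth, so loss of coverage at whole loci stays open. A difference in how positions were assigned to the same reads may account for partner sites, which was not tested.

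CGG and CCG are reverse complements and so equally frequent over both strands, and calls of modification confined to CG would favour CGG. At shared sites with a level of at least 80% the ratio was 1.11 (interval 0.781 to 1.57), far from such an excess if positions are as listed. These sites have the same position in both replicates, but their counts are not independent, so a shift carried into both could draw the ratio toward 1, and modification confined to CG stays open. Over all shared sites it was 1.20 (1.02 to 1.41), but 1.17 (0.985 to 1.38) outside the dense windows, which includes 1, and 1.07 (0.961 to 1.19) and 1.24 (1.12 to 1.38) at all sites of replicates 1 and 2. The CTG to CAG ratio, which involves no CG, was itself 0.863 (0.798 to 0.934), so a mirror ratio strays from 1 without CG and unconverted cytosine regardless of context cannot be told apart from modification.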
